A study of Homo sapiens with 6 samples.

How the data were processed

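RNA sequencing was done on DU145 cells, an established human prostate cancer cell line, grown from spheres and kept for 7 days in DMEM/F12 at 37 °C and 5% CO2 either without serum (sphere group) or with serum (adherent group), with 3 libraries per group. Per the labels, RNA was taken with TRIzol and 0.4 µg of total RNA went into Illumina libraries. Whether the libraries were enriched for poly(A) RNA, and whether they kept the strand, is not given in the sources used here. The labels number the libraries 1 to 3 in each group and do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

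The authors deposited 1 table of FPKM values (expression scaled for gene length and library size) for 58735 genes, with gene coordinates, lengths and biotypes. Per the submitters' processing notes, reads were counted per gene with featureCounts 1.5.0-p3 on the build hg38. The aligner, the filters and the formula for FPKM are not given in the sources used here. Coordinates of all 58735 genes were the same as in GENCODE release 29 on GRCh38, and 58708 gene names were the same. Gene symbols in the text come from a table of current names.

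The table holds no read counts, but the FPKM times the gene length fell on whole multiples of a single step in each library, within 0.02 of a whole read in 100% of the values checked, which were those under 1000 reads. The reads recovered in this way summed to 15890030, 16629368 and 14147420 in adherent replicates 1 to 3 and to 15458101, 16217139 and 14279614 in sphere replicates 1 to 3. A read of a gene of 1 kb was worth 0.0602 to 0.0706 FPKM. The divisor of each library was not the plain sum of reads. It came out as a median-of-ratios size factor times the geometric mean of the sums, an inference from the values, so the deposited FPKM already carry a scaling between libraries.

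Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, 16892 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p below 0.05). All changes are sphere minus adherent on the log2(FPKM + 1) scale, which understates the change of genes with low values. Ratios of mean FPKM are given where both groups had enough reads. Gene lists, 35 in number with 815 entries, were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Of the entries, 814 were found in the table. The 33 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Counts of list members are given over all genes tested. Counts adjusted over the list alone are given where they differ.

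The named genes are the 10 largest rises and 10 largest falls among protein-coding genes past the threshold whose groups do not overlap, up to 4 members of each list with the largest change among those past the threshold, 18 markers named whatever their values, and the 3 genes with the highest mean in each group. A few genes that this rule takes are not reported here. Other genes named were chosen after their values were seen, and the text says so. Reads of overlapping genes cannot be assigned with certainty, since strand is not known. Among the named genes, SLC5A3, IFITM1, EPCAM, TM7SF2, ALDOA, ENO2, LDHA, H2BC5, S100A4, ZEB1, HLA-C, C3, SLC7A5, CTSB, NPC1, RPL37, PECAM1, CDH1, MT-ND4, MT-ND4L and MT-CO3 overlap another annotated gene on the same strand, and UQCRQ, ACSS2, LOX, CLDN7, NPC1, RPL30, TP53INP1, KRT8, POU5F1 and CA9 overlap a protein-coding gene on the other strand. Further named genes, such as VIM and HK2, overlap a non-coding gene on the other strand.

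On simulated reads drawn for the real genes at the real depths, 200 genes changed 1.5-fold were recovered at 50.0%, 2-fold at 93.5% and 4-fold at 98.5%, and 0 genes were called when none was changed. In the simulated runs 5.74% to 9.09% of calls were false. These runs changed 200 genes and took the library divisors as known, while 10404 genes were called in the data. The false shares therefore do not describe the real calls. The alternatives were a pseudocount of 0.1, no filter, a minimum mean FPKM of 2, rescaling to equal sums, rescaling by median ratios, quantile normalization, robust empirical Bayes, a replicate block, each library left out, limma voom on the recovered reads, protein-coding genes alone, an absolute log2 change of at least 1, treat against 0.5, camera with an estimated correlation and fry. A correction of each library for GC content and gene length by lowess (span 0.3) was added after seeing the data. GC content came from the longest GENCODE transcript and was found for 99.953% of the tested genes. Python 3 scripts with pandas and numpy did the remaining steps.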

Results

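The data are FPKM values from 6 RNA-seq libraries of DU145 cells, a human prostate cancer cell line. Sphere-derived cells were kept for 7 days without serum, which gave 3 sphere libraries, or with serum, which gave 3 adherent libraries. The comparison asks how the expression of sphere cells differs from that of the same cells returned to serum and adherent growth. Serum and growth form changed together, so their effects cannot be told apart in any result below. Reads assigned to genes, recovered from the FPKM steps, numbered 14147420 to 16629368 in the adherent libraries and 14279614 to 16217139 in the sphere libraries. Genes with a value above 0 numbered 24738 to 25018 in the adherent libraries and 25992 to 27501 in the sphere libraries. In both groups the 3 genes with the highest mean were MT-CO1, MT-CO3 and MT-CO2, which encode cytochrome c oxidase subunits. MT-CO1 stood at 9828 ± 1248 FPKM (SD, n = 3) in adherent and 9792 ± 197 FPKM (SD, n = 3) in sphere cells.

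Libraries separated by culture condition. The first principal component of log2(FPKM + 1) held 83.1% of the variance and set the 3 sphere libraries apart from the 3 adherent libraries. Pearson correlations across the tested genes, which are not independent replicates, were 0.982 to 0.986 within the adherent group, 0.980 to 0.981 within the sphere group and 0.865 to 0.883 between groups. With limma, 10404 of 16892 tested genes passed an adjusted p of 0.05, of which 4997 were higher and 5407 lower in spheres. At an unadjusted p of 0.05 the count was 11103. With an absolute log2 change of at least 1 as well, 1331 genes were higher and 1119 lower. The 3 sphere libraries all lay above the 3 adherent libraries for 5541 genes and all below them for 5947 genes, together 68.0% of those tested, where chance gives 10%.

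**Figure D1:**
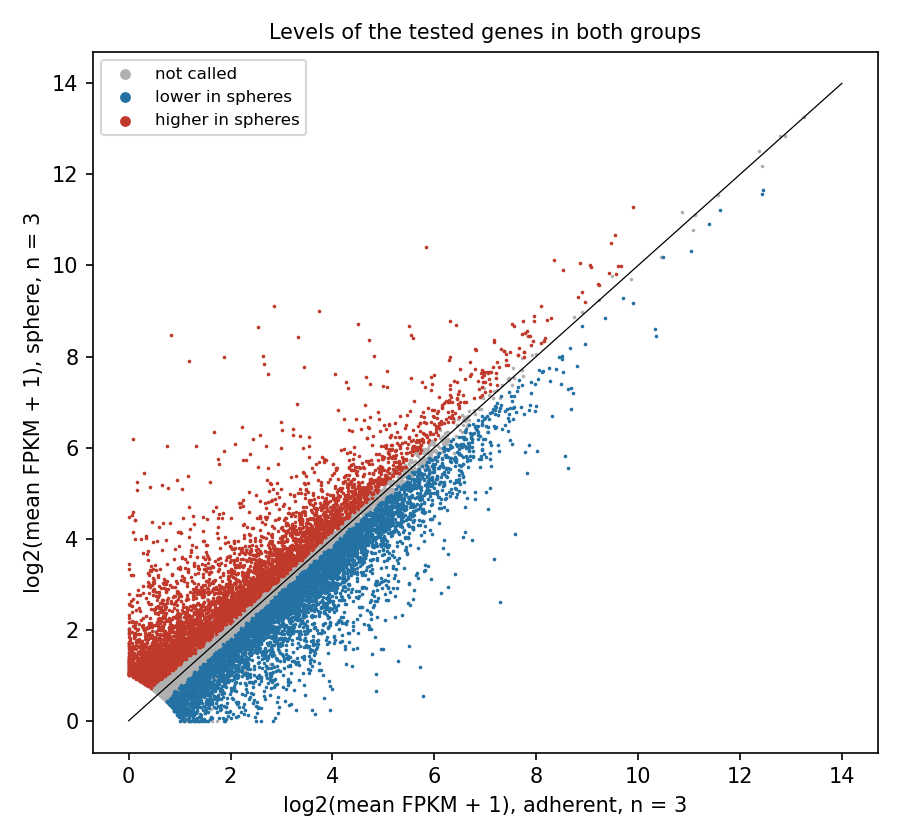
Mean levels of the 16892 tested genes as log2(mean FPKM + 1), adherent on the x axis and sphere on the y axis, with n = 3 libraries per group and the line of equal levels. Red points are the 4997 genes called higher in spheres, blue points the 5407 called lower, and grey points were not called.

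On the log2(FPKM + 1) scale, the largest rise among protein-coding genes was in SFTPB, which encodes surfactant protein B and lies on chromosome 2 from 85657314 to 85668741 (GRCh38, minus strand). SFTPB stood at 0.786 ± 0.068 FPKM (SD, n = 3) in adherent cells and at 353 ± 46.4 FPKM (SD, n = 3) in sphere cells, a log2 change of 7.62 ± 0.10 (SE, limma adjusted p = 8.04e-08). CEACAM6, a cell surface glycoprotein, rose from 1.28 to 238 FPKM. TXNIP, a thioredoxin-binding protein, rose from 2.64 to 251 FPKM, and IGFBP3, which binds insulin-like growth factors, rose from 4.83 to 400 FPKM. SLPI, a secreted protease inhibitor, rose from 5.22 to 256 FPKM. S100A14 and S100A9, which encode calcium-binding proteins, rose to 64.5 and 229 FPKM, and the interferon-induced genes IFI6 and IFITM1 rose to 511 and 71.4 FPKM. IFITM1 had 3 reads in the 3 adherent libraries together and overlaps IFITM2. SLC5A3, a myo-inositol transporter, rose from 6.22 to 548 FPKM, but its locus overlaps MRPS6 on the same strand and reads of the pair cannot be told apart.

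On the same scale, the largest fall among protein-coding genes was in EFEMP1, an extracellular matrix gene on chromosome 2 from 55865967 to 55924139 (GRCh38, minus strand). EFEMP1 went from 53.5 ± 3.80 FPKM (SD, n = 3) in adherent cells to 0.449 ± 0.118 FPKM (SD, n = 3) in sphere cells, a log2 change of -5.23 ± 0.08 (SE, limma adjusted p = 1.44e-07). CCN1, a matricellular protein, fell from 156 to 5.07 FPKM, and DKK1, a secreted Wnt inhibitor, fell from 51.3 to 1.28 FPKM. The microtubule-associated MAP1B fell from 27.8 to 0.574 FPKM, and the vitamin D hydroxylase CYP24A1 fell from 38.0 to 1.48 FPKM. ANTXR1 fell from 44.4 to 2.10 FPKM, MSRB3 from 14.6 to 0.170 FPKM and MYBL1 from 30.8 to 2.00 FPKM. The receptor tyrosine kinase AXL fell from 143 to 10.8 FPKM and the metallothionein MT1E from 191 to 16.2 FPKM.

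Cell division genes were lower in spheres. Of 29 tested genes of G2 and mitosis, 29 fell, with a median log2 change of -2.18 (camera adjusted p = 6.48e-14, and adjusted p = 0.411 with an estimated correlation). MKI67, a marker of proliferating cells, fell from 55.6 ± 2.86 to 9.78 ± 2.29 FPKM (SD, n = 3 each), and CDC20, KIF23, TPX2 and BIRC5 fell 7.23, 8.49, 6.10 and 6.22 times in mean FPKM. Of 32 S phase and replication genes, 29 fell and 0 rose, with a median of -1.26 (camera adjusted p = 7.56e-11, and adjusted p = 0.401 with an estimated correlation). UHRF1 fell from 46.6 to 5.36 FPKM, RRM2 from 18.1 to 1.97 FPKM, CDC45 from 23.5 to 3.34 FPKM and TK1 from 133 to 23.9 FPKM. Replication-dependent histone genes went the other way. Of 12 tested, 9 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 0.00513, and adjusted p = 0.352 with an estimated correlation). H2BC5 rose from 23.7 to 96.6 FPKM, H2BC4 from 12.7 to 32.4 FPKM, H2AC6 from 42.6 to 89.8 FPKM and H2BC21 from 18.4 to 35.9 FPKM. Most histone mRNA lacks a poly(A) tail. The median log2 change was 0.39 over 175 snRNA genes, 0.31 over 167 miscellaneous RNA genes and 0.07 over 126 snoRNA genes. It was 0.22 over 143 genes of unproven coding status (TEC), 0.16 over 190 unprocessed pseudogenes, 0.15 over 1126 antisense genes and 0.13 over 853 lincRNA genes. Over 12307 protein-coding genes it was -0.07. The snRNA genes RNU4-1, RNU5B-1, RNU11 and RNU12 were listed at 0 in all libraries, so the snRNA median rests on other entries. These medians therefore do not measure the share of RNA without a poly(A) tail. Of 22 quiescence and FOXO-associated genes, 17 rose and 4 fell, with a median of 0.97 (camera adjusted p = 6.47e-05, and adjusted p = 0.401 with an estimated correlation). BCL6, YPEL3 and ARRDC3 rose 7.53, 4.59 and 4.26 times.

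Interferon-stimulated genes were higher in spheres. Of 31 tested, 31 rose, with a median log2 change of 2.04 (camera adjusted p = 2.38e-14, and adjusted p = 0.401 with an estimated correlation). OAS3 rose from 4.41 ± 0.30 to 72.0 ± 8.21 FPKM (SD, n = 3 each), and OAS1 rose from 0.059 to 22.9 FPKM. Of 23 NF-kappaB and inflammatory genes, 15 rose and 4 fell, with a median of 0.91 (camera adjusted p = 0.000363, and adjusted p = 0.430 with an estimated correlation). The chemokines CCL5 and CCL20 rose from 0.114 to 32.5 FPKM and from 1.92 to 20.7 FPKM. LCN2, an iron-siderophore binding protein, rose from 0.933 to 37.9 FPKM and complement C3 from 2.01 to 36.6 FPKM. Of 17 antigen presentation genes, 10 rose and 1 fell, and the list did not pass (median 0.44, camera adjusted p = 0.0574). HLA-E rose 2.17 times, PSMB10 2.04 times, HLA-F 1.89 times and HLA-C 1.67 times, and reads of HLA genes can be shared between near-identical copies. Without adherent replicate 3 or sphere replicate 2 the list passed (camera adjusted p = 0.0462 and 0.0183), as it did with quantile normalization, voom, protein-coding genes alone, a mean FPKM of at least 2 and the GC and length correction added after seeing the data (0.0219 to 0.0449).

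Epithelial genes were higher and targets of YAP/TAZ and SRF lower in spheres. Of 24 epithelial genes, 22 rose and 2 fell, with a median log2 change of 1.65 (camera adjusted p = 8.66e-09, and adjusted p = 0.315 with an estimated correlation). CDH1, which encodes E-cadherin, rose to 63.7 ± 0.97 FPKM (SD, n = 3) with a log2 change of 1.59 ± 0.05 (SE), the desmosomal DSP from 25.3 to 328 FPKM, the tight junction claudins CLDN4 and CLDN7 to 76.8 and 76.1 FPKM, and the splicing regulator ESRP1 from 2.60 to 22.6 FPKM. The 2 that fell, named after their values were seen, were the tight junction genes CLDN1 and TJP1, with log2 changes of -1.91 and -1.44. Of 20 YAP/TAZ targets, 17 fell and 1 rose, with a median of -1.29 (camera adjusted p = 3.91e-07, and adjusted p = 0.388 with an estimated correlation). CCN2 and ANKRD1 fell, with log2 changes of -3.19 and -3.35, from 19.8 FPKM in adherent cells for CCN2 and to 0.183 FPKM in spheres for ANKRD1. MYOF, also named after its value was seen, was the 1 that rose. Of 20 serum-induced SRF and actin cytoskeleton genes, 17 fell and 0 rose, with a median of -0.96 (camera adjusted p = 7.17e-07, and adjusted p = 0.358 with an estimated correlation). ACTB fell from 1313 to 347 FPKM, FLNA from 225 to 42.2 FPKM, MYL9 from 50.5 to 7.74 FPKM and TPM1 from 7.14 to 0.664 FPKM. Mesenchymal genes went both ways. Of 10 tested, 5 rose and 4 fell (median 0.36, camera adjusted p = 0.620). VIM, which encodes vimentin, fell from 76.2 to 42.8 FPKM and ZEB1 from 2.35 to 0.635 FPKM, while S100A4 rose from 18.4 to 173 FPKM and COL6A1 from 21.4 to 44.0 FPKM. Of 22 integrin and laminin genes, 10 rose and 11 fell (median -0.10, camera adjusted p = 0.638), with log2 changes of -2.81 for THBS1 and 1.94 for LAMB2. Of 20 TGF-beta targets, 5 rose and 12 fell (median -0.45, camera adjusted p = 0.0938), among them TGFBI, which fell 5.43 times, and BHLHE40, which rose 5.47 times. Of 20 immediate early genes, 8 rose and 7 fell (median 0.09, camera adjusted p = 0.474). FOS rose 12.8 times and FOSL1 fell 7.83 times.

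**Figure D2:**
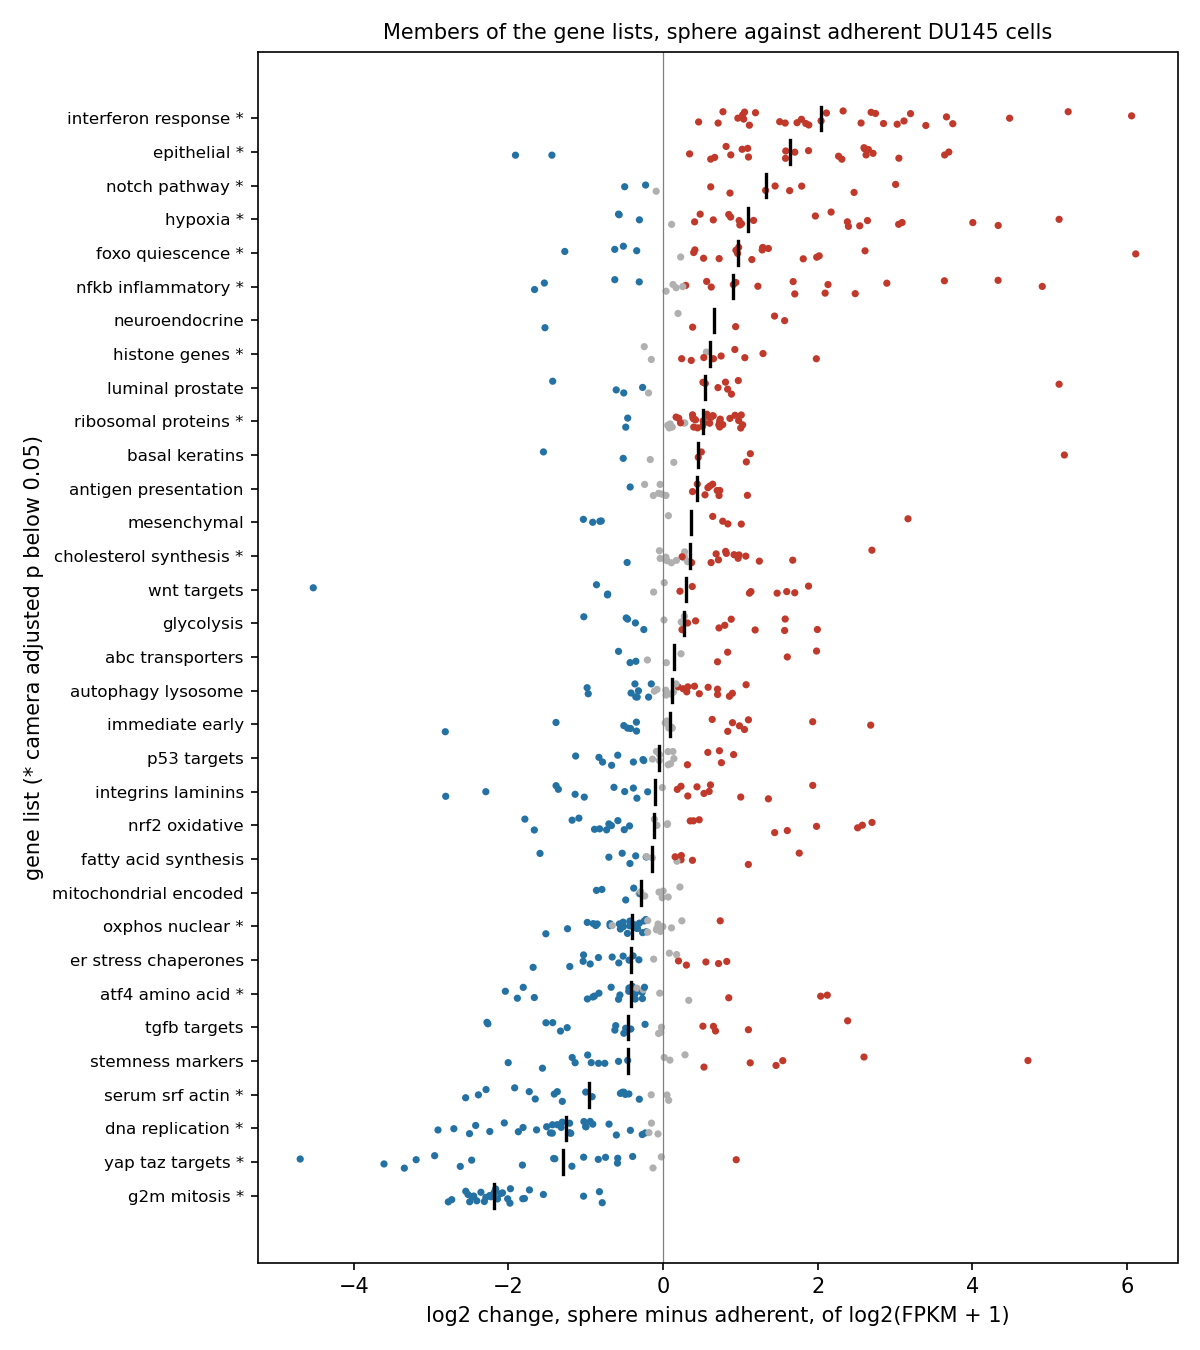
Log2 change, sphere minus adherent, of each tested member of the 33 gene lists with at least 5 tested members, with a black bar at the list median. Red and blue points passed the adjusted p of 0.05 as higher or lower, grey points did not. The medians run from -2.18 for G2 and mitosis to 2.04 for interferon response, and the 15 lists with an asterisk passed camera with the preset correlation.

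Hypoxia targets were higher and respiratory chain genes lower in spheres. Of 24 HIF targets, 20 rose and 3 fell, with a median log2 change of 1.09 (camera adjusted p = 8.82e-08, and adjusted p = 0.315 with an estimated correlation). NDRG1 rose from 8.95 ± 0.11 to 346 ± 14.3 FPKM (SD, n = 3 each), ADM from 0.707 to 33.4 FPKM, ANGPTL4 from 3.23 to 66.8 FPKM and LOX from 0.573 to 12.5 FPKM. CA9 was at or below 0.0404 FPKM in the mean of either group and was not tested. Of 19 glycolysis genes, 10 rose and 5 fell (median 0.28, camera adjusted p = 0.0604), and HK2, ALDOA, ENO2 and LDHA rose 4.49, 3.51, 3.20 and 2.29 times. Without adherent replicate 2 or sphere replicate 1 this list passed (camera adjusted p = 0.0431 and 0.0386), as it did with voom, protein-coding genes alone and a mean FPKM of at least 2 (0.0273 to 0.0421). Of 37 nuclear genes of the respiratory chain and ATP synthase, 26 fell and 1 rose (27 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 4.08e-05, and adjusted p = 0.492 with an estimated correlation). ATP5MC1 fell 3.02 times, UQCRQ 2.39 times, COX5A 2.00 times and CYCS 1.90 times. Of 13 mitochondrially encoded genes, 5 fell and 0 rose (median -0.29, camera adjusted p = 0.140). MT-ND4L and MT-ND4, which overlap, fell 1.82 and 1.74 times, and MT-ND1 and MT-ND2 fell, with log2 changes of -0.48 and -0.38. With no filter on low values these 4 genes were not called, nor were MT-ND2 and MT-ND4 with quantile normalization.

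Sterol genes were higher in spheres. Of 26 cholesterol synthesis and SREBP2 target genes, 14 rose and 1 fell, with a median log2 change of 0.34 (camera adjusted p = 0.000857, and adjusted p = 0.607 with an estimated correlation). TM7SF2 rose 3.43 times, MSMO1 2.46 times and INSIG1 2.18 times. HMGCS1, an early enzyme of the pathway, rose from 26.7 ± 1.48 to 42.1 ± 8.61 FPKM (SD, n = 3 each). Fatty acid synthesis genes went both ways, with 6 of 15 higher and 6 lower (median -0.14, camera adjusted p = 0.911). The desaturase SCD rose from 324 to 1104 FPKM and ACSS2 rose 2.26 times, while ELOVL6 fell 3.65 times and ME1 1.66 times.

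Stemness markers did not move together. Of 19 tested, 6 rose and 10 fell, and the median was -0.46, the mean 0.10 and the camera direction downward (adjusted p = 0.612), while fry, which does not compare the list with other genes, gave an upward direction (adjusted p = 0.00298). CD44 fell from 12.5 ± 0.15 to 6.57 ± 0.26 FPKM (SD, n = 3 each, log2 change -0.83 ± 0.05, limma adjusted p = 1.42e-05), BMI1 from 47.1 to 23.5 FPKM and the integrin ITGA6 fell to 9.89 FPKM (log2 change -1.14). CD24 fell 4.10 times and EZH2 3.23 times. KLF4 rose from 4.56 to 15.3 FPKM, the chemokine receptor CXCR4 to 64.9 FPKM (log2 change 4.72) and EPCAM from 32.8 to 204 FPKM. MYC was 47.7 ± 2.11 FPKM in adherent and 48.3 ± 4.33 FPKM in sphere cells (SD, n = 3 each, limma adjusted p = 0.874). ALDH1A1 and NANOG were listed at 0 in all 6 libraries, PROM1 and SOX2 stayed below 0.03 FPKM in the mean of either group, and POU5F1 was 0.351 FPKM in adherent and 0.204 FPKM in sphere cells. These 5 genes were below the level tested.

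**Figure D3:**
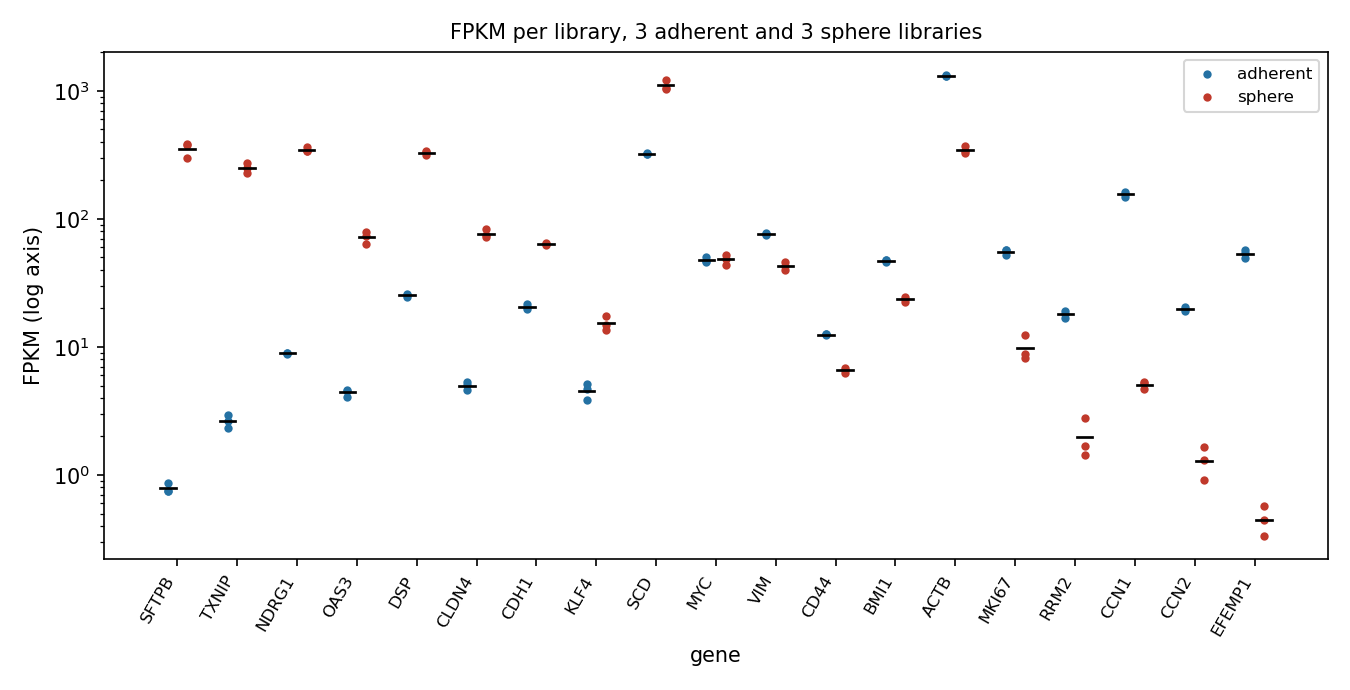
FPKM of 19 named genes in each library on a log axis, with blue points for the 3 adherent libraries, red points for the 3 sphere libraries and black bars at the group means. Of these genes SFTPB spans the widest gap upward, from 0.786 to 353 FPKM in the means, EFEMP1 the widest downward, from 53.5 to 0.449 FPKM, and the MYC values of both groups overlap.

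Lineage and pathway lists differed in outcome. Of 11 Notch pathway genes, 8 rose and 2 fell, with a median log2 change of 1.33 (camera adjusted p = 0.00827, and adjusted p = 0.465 with an estimated correlation). The receptor NOTCH3 rose from 6.94 to 62.9 FPKM and the targets HES1 and HES4 rose 6.77 and 3.23 times, with LFNG rising 7.46 times. Of 14 Wnt targets, 8 rose and 4 fell (median 0.30, camera adjusted p = 0.270), with rises in SP5 and NOTUM of 4.53 and 4.95 times and in NKD1 to 3.12 FPKM (log2 change 1.70) beside the fall of DKK1. Of 13 luminal prostate genes, 8 rose and 4 fell (8 and 5 adjusted over the list alone, median 0.55, camera adjusted p = 0.185). KRT8, which overlaps KRT18 on the other strand, rose from 138 to 201 FPKM. PMEPA1 fell 2.99 times, ACP3 rose from 0.056 to 1.07 FPKM and STEAP4 from 0.056 to 0.950 FPKM. Of 9 basal keratin and squamous genes, 5 rose and 2 fell (median 0.46, camera adjusted p = 0.297), with DSC3 falling from 2.33 to 0.137 FPKM and S100A8 and KRT6A reaching 1.42 and 1.13 FPKM. Of 6 neuroendocrine genes, 4 rose and 1 fell (median 0.66, camera adjusted p = 0.103). UCHL1 fell 2.89 times, DLL3 rose 3.25 times and SNAP25 3.78 times.

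Of 37 ribosomal protein genes, 29 rose and 2 fell (30 and 2 adjusted over the list alone), with a median log2 change of 0.52 (camera adjusted p = 3.91e-07, and adjusted p = 0.492 with an estimated correlation). RPL30, RPS9 and RPL37 rose 2.05, 2.01 and 1.98 times, and reads of ribosomal protein genes can be shared with their pseudogenes. Of 26 ATF4 and amino acid genes, 19 fell and 3 rose (20 and 3 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.00329, and adjusted p = 0.580 with an estimated correlation). CHAC1 fell 4.44 times and the amino acid transporter SLC7A5 3.75 times, while GDF15 and NUPR1 rose 7.45 and 6.10 times. Of 20 endoplasmic reticulum chaperone genes, 12 fell and 5 rose (median -0.41, camera adjusted p = 0.0938), with SDF2L1, PDIA4, MANF and HYOU1 falling 3.43, 2.33, 2.21 and 2.09 times. Of 25 NRF2 targets, 9 rose and 12 fell (median -0.11, mean 0.12, camera downward with adjusted p = 0.638, fry upward with adjusted p = 0.00666), and AKR1C1, AKR1C3 and AKR1C2, which are similar in sequence, rose 8.82, 6.47 and 7.73 times. Of 28 autophagy and lysosome genes, 12 rose and 9 fell (median 0.12, camera adjusted p = 0.381), with CTSB and NEU1 rising 2.12 and 1.94 times and CTSL and NPC1 falling 1.99 and 2.00 times. Of 22 p53 targets, 5 rose and 8 fell (median -0.05, camera adjusted p = 0.866), with AEN, SESN2 and PHLDA3 falling 2.70, 1.87 and 1.85 times and TP53INP1 rising 2.36 times. Of 10 ABC transporters, 4 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 0.488), with ABCC2, ABCC3, ABCC4 and ABCG1 rising 4.98, 3.16, 1.86 and 3.46 times.

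Markers of other cell types were mostly below the level tested. Of 12 immune genes, 1 was tested, CD14, named after its value was seen, at 1.25 ± 0.42 FPKM in adherent and 1.82 ± 0.22 FPKM in sphere cells (SD, n = 3 each, limma adjusted p = 0.0890). Of 12 endothelial and erythroid genes, 1 was tested, PECAM1, which rose from 0.048 to 4.25 FPKM (limma adjusted p = 3.26e-06). None of the 15 list calls of camera held with an estimated correlation. The histone list lost its call (camera adjusted p from 0.00513 to 0.352) although its estimated correlation, -0.0087, was below the preset 0.01. That loss therefore does not come from a higher correlation among its members. Both forms of camera also differ in degrees of freedom, since the form with an estimated correlation uses the residual number, 4 here. The adjusted p-values with an estimated correlation thus do not show the effect of correlation alone, and the share of each part was not tested.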

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

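The GC and length correction was added after seeing the data, and all other alternatives were planned. The count of 10404 genes stayed within 1.5 times of itself under every alternative that set no minimum change, from 8128 at a mean FPKM of at least 2 to 11215 with no filter, and 10504 were called after the GC and length correction. More genes were lower than higher except when rescaled by median ratios (5255 higher, 5131 lower), with no filter (5746 higher, 5469 lower) and with an absolute log2 change of at least 1. The count was 2450 with an absolute log2 change of at least 1 (1331 higher, 1119 lower) and 3605 with treat against 0.5 (1780 higher, 1825 lower), which follows from the minimum change they set. Deviations of same-numbered libraries correlated at 0.106, 0.042 and 0.034. Sphere replicate 3 correlated best with adherent replicate 2 (0.037), so replicates 2 and 3 were not clearly paired. Replicates 1 of both groups stood together on the second principal component (5.06% of the variance). There adherent replicate 1 was at 17.9 and sphere replicate 1 at 17.8, with the other libraries from -12.2 to -5.28. Whether replicates 1 shared a batch was not tested. With the replicate block, 10285 genes and 15 lists were called. The lists called numbered 15 to 17 under the other alternatives, 0 with an estimated correlation and 30 with fry, which does not compare a list with other genes. Robust empirical Bayes was not run for the lists, since camera has no such option. The gap between the lowest correlation within a group and the highest between groups, 0.0965, was 0.119 with a pseudocount of 0.1, 0.04697 with no filter, 0.161 at a mean FPKM of at least 2, 0.108 rescaled to equal sums, 0.118 for protein-coding genes and 0.0965 to 0.106 with 1 library left out, and the cause was not tested. Of 157 tested named genes, 123 kept their direction and side of the threshold under every alternative. Those that turned had not been called. MYC ranged from -0.0436 to 0.0833 with 1 library left out, MT-CO1 from -0.0690 to 0.102 and MT-CO3 from -0.112 to 0.0172, and MT-CO2 was -0.00148 after the GC and length correction. MT-ND1, MT-ND2, MT-ND4 and MT-ND4L lost their calls with no filter, and MT-ND2 and MT-ND4 with quantile normalization. The minimum changes ended 30 calls (absolute log2 change of at least 1) and 12 calls (treat). For 4 lists that camera had not called, the tested direction turned from lower to higher while the median stayed below 0. For fatty acid synthesis this median was -0.139 at a mean FPKM of at least 2, for protein-coding genes and under fry, -0.0371 with quantile normalization and -0.178 to -0.0754 with 1 library left out (turned without sphere replicate 1), for p53 targets -0.04704 for protein-coding genes and under fry and -0.0266 after the GC and length correction, for stemness markers -0.458 and for NRF2 targets -0.113 under fry (fry adjusted p = 0.00298 and 0.00666), and the cause was not tested. Antigen presentation and glycolysis passed camera at a mean FPKM of at least 2 (adjusted p = 0.0219 and 0.0421), for protein-coding genes and with voom, and antigen presentation also with quantile normalization (0.0449) and after the GC and length correction (0.0361), with adjusted p of 0.0183 to 0.0803 and 0.0273 to 0.193 over the camera alternatives with the preset correlation, and TGF-beta targets and endoplasmic reticulum chaperones passed with no filter. In a gene of 1 kb 1 read was worth 0.0602 to 0.0706 FPKM, so depth limits levels near that.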

Other observations

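The genes and families in this paragraph were chosen after their values were seen and were not tested for enrichment. The counts for metallothioneins and for secreted and mucosal genes were the same under each rescaling tried and after the GC and length correction. Of 11 metallothionein genes in the table, 7 were tested and fell. MT2A fell to 45.6 ± 6.73 FPKM (SD, n = 3), a log2 change of -3.08 ± 0.11 (SE). Of 15 secreted and mucosal genes looked at, 8 were tested and rose, and 7 were below the level tested, among them LTF, SCGB1A1 and SCGB3A2, listed at 0 in all libraries. MUC1 went from 30.8 to 163 FPKM, WFDC2 from 4.20 to 57.3 FPKM, DMBT1 from 0.235 to 42.2 FPKM and MUC5B from 0.0034 to 9.09 FPKM. The aquaglyceroporin AQP3 rose from 56.3 to 1352 FPKM and the betaine transporter SLC6A12 from 0.389 to 9.06 FPKM. Of 24 tested HOX genes, 11 fell, 3 rose and 10 were not called (11 to 12 fell and 3 to 5 rose under those settings), with HOXB9 falling to 1.97 FPKM (log2 change -2.82).

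Of the tests below, only that of non-coding genes on the shifted chromosomes was fixed before its result was seen. The others were chosen after the pattern they bear on was seen, including both counts of splits.

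Genes of whole chromosomes shifted together. Among 12279 protein-coding genes, 6 of 23 chromosomes passed an adjusted p of 0.05 in 10000 shuffles of blocks of 20 neighbouring genes, which argues against chance placement of changed genes, with medians relative to all genes of 0.25 on chromosome 8, 0.22 on 19, -0.21 on 5, -0.21 on 15, -0.20 on 18 and -0.20 on 7, there mostly on the long arm (-0.25 against -0.05 on the short arm). GC content and gene length do not account for chromosomes 5, 7, 8, 15 and 19, whose highest adjusted p after correction was 0.00092, although the median of chromosome 19 went from 0.22 to 0.13, whereas chromosome 18 ended at an adjusted p of 0.0862 (median from -0.20 to -0.15) and stays open. A difference in chromosome copy number between the cultures may underlie part of this, but non-coding genes that overlap no protein-coding gene followed with an interval that excludes 0 on 2 of the 6 chromosomes, 7 and 8, and on chromosome 19 their shift was -0.16 (95% bootstrap interval -0.30 to 0.08), which leaves out the protein-coding shift, while on chromosomes 5, 15 and 18 the intervals included 0 and on 18 the shift was 0.04. An earlier form of this test, on blocks of protein-coding genes of 4 of the chromosomes and with a bound set after block values had been seen, was dropped for that reason, and regulation that differs along chromosomes stays open beside copy number, as no DNA data were used here.

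Histone genes were higher while replication genes were lower. Reads moved between near-identical histone copies would leave the sum over copies unchanged, yet the summed reads of 65 replication-dependent histone genes, in CPM, were 1.6 times higher in spheres (494 ± 10.6 against 791 ± 18.1, SD, n = 3 each) with no overlap. A larger share of RNA without a poly(A) tail in the sphere libraries may account for it and cannot be told apart from a change in the cells. Of 24 entries for abundant RNAs of that kind only 2 reached the level tested, and their median log2 change of 1.02 met the bound set, but 1 of them had 5 reads in all, so the test was taken as void under a minimum of 5 genes set after this was seen. RN7SL2, the other, was 949 ± 517 FPKM in adherent and 2493 ± 719 FPKM in sphere cells, while RNU4-1, RNU5B-1, RNU11 and RNU12 were listed at 0 in all libraries.

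Some surfactant and lung-associated genes rose in spheres of a prostate line. Of 18 entries, chosen after their values were seen and not tested for enrichment, 12 were tested, of which 9 rose, 1 fell and 2 were not called (11 and 1 under 3 of the rescalings), with NAPSA rising from 9.91 to 217 FPKM and SFTA1P falling from 43.5 to 5.01 FPKM, and NKX2-1, a lung and thyroid transcription factor, was 45.0 ± 4.29 FPKM in adherent and 52.3 ± 3.33 FPKM in sphere cells (SD, n = 3 each). Admixed alveolar type II cells would bring the abundant SFTPC, which stood at no more than 0.114% of SFTPB in any sphere library, and SFTPA1 and SFTPA2, which were at 0.0171 and 0.0078 FPKM. NKX2-1 mRNA rose little, with a log2 change of 0.22 ± 0.08 (SE, limma adjusted p = 0.0523), and was called higher under 3 of the rescalings. A large rise in NKX2-1 mRNA therefore does not account for the pattern, by a bound set after its value was seen. A small rise stays open, and the activity of the protein was not measured. The culture condition itself stays open and was not tested, and the identity of the line cannot be tested from these values.

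The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10404 genes and the highest of the others 0, so 1 of the 10 gave as many. For the lists, the real split gave 15 and the highest of the others 15, so 2 of the 10 gave as many. The other 9 splits, which mix the groups and called 0 genes, each called 10 to 15 lists. Each sets 2 libraries of 1 group and 1 of the other against the rest, so part of the sphere-adherent difference stays in it. These list counts therefore cannot tell how strong a camera call with the preset correlation is.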
